A study of Homo sapiens with 3 samples.

How the data were processed

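Gene expression was measured by RNA sequencing in HCT116 cells, a human colorectal carcinoma line, after retroviral transduction and selection with puromycin at 1 µg/ml. The 3 libraries came from cells carrying a control shRNA, ETV1 shRNA #1 or ETV1 shRNA #5, with 1 library per group, and groups were taken from the treatment labels. Short hairpin RNAs (shRNAs) are transcripts that the cell processes into small RNAs directed against a chosen messenger RNA.

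The main table held 40448 gene rows of a RefSeq gene model, per the file headers. Its values were deposited by the authors as log2 values under columns named normalized. Raised from the log2 scale, low values were whole numbers or simple fractions with the same steps in every library. Of the values between 1 and 5, 59.4% (control), 60.5% (#1) and 59.2% (#5) were whole within a tolerance of 0.001, against 5.32%, 5.51% and 4.85% of the values from 100 to 1000. The column totals differed between libraries. The deposited log2 values were therefore read as log2 of estimated, partly fractional reads per gene, floored at 1 read and not scaled between libraries. A listed 0 stands for 1 read or fewer and was set to 0 reads. The aligner, the counting program and their versions were not given in the sources used here. Whether counting used strand or shared reads between overlapping genes is likewise not given in the sources used here, so overlapping, antisense and near-identical genes are uncertain.

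The submitters' processing notes list GRCh38. Of 37994 rows matched to RefSeq on GRCh38 by Entrez number, 0.284% had the same start, so the coordinates in the main table belong to another build and are not printed. The other table held the union of the authors' 3 comparisons of 1 library with 1, made with a Z test on Ensembl genes, per the file headers. It gives the authors' p-values and corrected p-values, a ratio (absolute fold change), a signed fold change given as a number with no other unit, and log2 fold changes, and its log2 values per library were centred by the authors on each gene's median. Genes passed at 2-fold or more and a corrected p of 0.05 or less, per the file headers. The regions of the Venn diagram named in the header leave out genes that pass all 3 tests, and 0 genes with values in all 3 were found, so counts from the authors' deposited table omit such genes. Gene starts in it equalled those of GENCODE 29 on GRCh38 in 97.0% of 5203 matched rows.

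Reads were scaled to a library of 1000000 (RPM) with trimmed mean of M values (TMM) factors, trimming 30% of log ratios and 5% of abundances, written in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3. The factors were 1.03 (control), 0.968 (#1) and 1.00 (#5). The planned count model was replaced because the values are log2 of estimated reads. Its stated substitute was used, log2(RPM + 1), for the 13024 genes with a mean of 1 RPM or more over the 3 libraries. A log2 ratio is a difference on this scale, which understates the change of low genes. Differences of 1 or more in size are called 2-fold.

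With 1 library per group there was no replicate error, and each comparison of a hairpin with the control compares those libraries. One model had residual degrees of freedom, namely 1. In it the 2 hairpin libraries formed an arm against the control library, and limma 3.58.1 in R 4.3.3 was run with a mean-variance trend and Benjamini-Hochberg adjustment. Its spread is that between the 2 hairpins, which also differ in sequence, and the lone control library is assumed to vary like them. With 1 library for the control and for each hairpin, no replicate culture was measured. The model's p-values therefore measure only the spread between these libraries. The same step was tested on simulated reads for this comparison. At a simulated coefficient of variation of 0.1, over 12997 genes, it called 96.0% of the 2-fold and 100% of the 4-fold changes, with 6 unchanged genes called. At 0.2, over 13000 genes, it called 5.15% and 88.4%, with 1 unchanged gene called. Every simulated gene had the same coefficient of variation, while the spread that limma fitted to the real libraries differed between genes. These percentages therefore do not give the power of the step on the real libraries.

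The 36 gene lists, with 916 entries, were fixed before the data were examined, as were the tests, the named-gene rule and the alternatives not marked as later additions. A list needed 5 measured members, which 30 lists had. Its median log2 ratio was placed among 10000 random lists of the same size, drawn from the same 20 bins of mean expression, as a description of these libraries. The middle 95% of random medians, from percentile 2.5 to 97.5, is called the matched range. Members were also counted past limma's test over all genes and adjusted over the list alone.

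Named genes were ETV1, KDM3A and FOXQ1, and the 12 genes each way with the largest smaller-of-both ratio among genes 2-fold changed the same way with both hairpins. Those needed a mean of 5 RPM and a symbol that is not a clone or placeholder name. The rule added the 5 genes each way with the largest difference between the hairpins, and up to 4 members of each list, taken by the size of the smaller ratio among those changed the same way with both hairpins.

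Comparisons with a shared control correlate by construction, even where nothing changed. Unchanged libraries sharing a control were simulated 200 times with counting error alone, taking 2 reads per fragment as an assumption. Another 200 simulations drew each gene's variance at random from the distribution that limma fitted to the spread between the 2 hairpin libraries. The latter step was repeated for the lists, with 1000 random lists each and genes drawn independently. Transcript length and GC content came from the longest GENCODE 29 transcript, for 98.4% of the tested genes. Alternatives were other scalings (median of ratios, total reads), other filters, pseudocounts of 0.1 and 5, fold rules of 1.5 and 3, and lists without their most changed member. Subtraction of length and GC trends, removal of readthrough loci with their component genes and pseudogenes, and the authors' deposited table were added after seeing the data. Other tools were scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9. The submitters' per-library values in the table of Z tests, being centred per gene, were not used as levels.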

Results

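To examine what the ETS-family transcription factor ETV1 does in colon cancer cells, RNA was sequenced from HCT116 cells carrying a control shRNA or one of 2 hairpins against ETV1, named #1 and #5. Each group had 1 library, so values below carry no replicate error. The libraries held 64415216 (control), 61058290 (#1) and 78507079 (#5) estimated reads in genes, and 22459, 23067 and 22383 of the 40448 gene rows were listed at 0. Of these rows, 13024 genes reached a mean of 1 RPM (reads scaled to a library of 1000000) and were compared. Log2 ratios are differences of log2(RPM + 1) from the control library.

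ETV1 itself (Entrez gene 2115; GRCh38 chromosome 7, 13891228 to 13991425, in the authors' deposited table) was lower with both hairpins. It stood at 18.8 RPM in the control library, 3.46 with #1 and 3.31 with #5, log2 ratios of -2.15 and -2.20, from 1247, 205 and 260 estimated reads. The libraries thus followed their labels at the targeted gene. The histone demethylase gene KDM3A was at 65.4 RPM in the control library, 44.7 with #1 and 54.3 with #5 (log2 ratios -0.54 and -0.26). FOXQ1, a forkhead transcription factor gene, lay below the expression minimum at 0.972, 0.254 and 0.352 RPM. The authors' deposited table gives log2 changes of -1.91 and -1.62 for FOXQ1, and -2.45 and -2.46 for ETV1.

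More genes were lower than higher with each hairpin. With #1, 171 genes were 2-fold or more higher and 408 lower. With #5, 168 were higher and 311 lower. In the same direction with both hairpins, 45 genes were higher and 125 lower. Across genes, which are not independent replicates, the log2 ratios of the hairpins had a Pearson r of 0.62 and a Spearman rho of 0.61, and 71.8% had the same sign. These comparisons share 1 control library, which cannot be split, so part of the overlap may come from that library. Unchanged libraries simulated with the variance seen between the hairpins gave r = 0.50, the same sign for 66.7% of genes, and on average 39.7 genes higher (range 17 to 60) and 40.0 lower (range 20 to 60) with both. The observed 45 higher genes lay inside that range and the 125 lower genes outside it. For #1 alone the simulation gave on average 159 higher (range 127 to 198) and 159 lower (range 131 to 187). The 171 higher genes with #1 thus lay inside the simulated range and the 408 lower genes outside it. This simulation had no floor at 0 reads and used only the main filter and pseudocount. Shared lower genes numbered 78 with a minimum of 5 RPM and 32 with a pseudocount of 5, which were not set against a simulation. Simulated counting error alone gave r = 0.50, the same sign for 66.8%, and 0 shared genes either way. Independent lists of these sizes would share 2.21 higher and 9.74 lower genes. The covariance of the log2 ratios was 0.141, against 0.0834 simulated with the hairpin variance and 0.00386 with counting error.

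**Figure D1:**
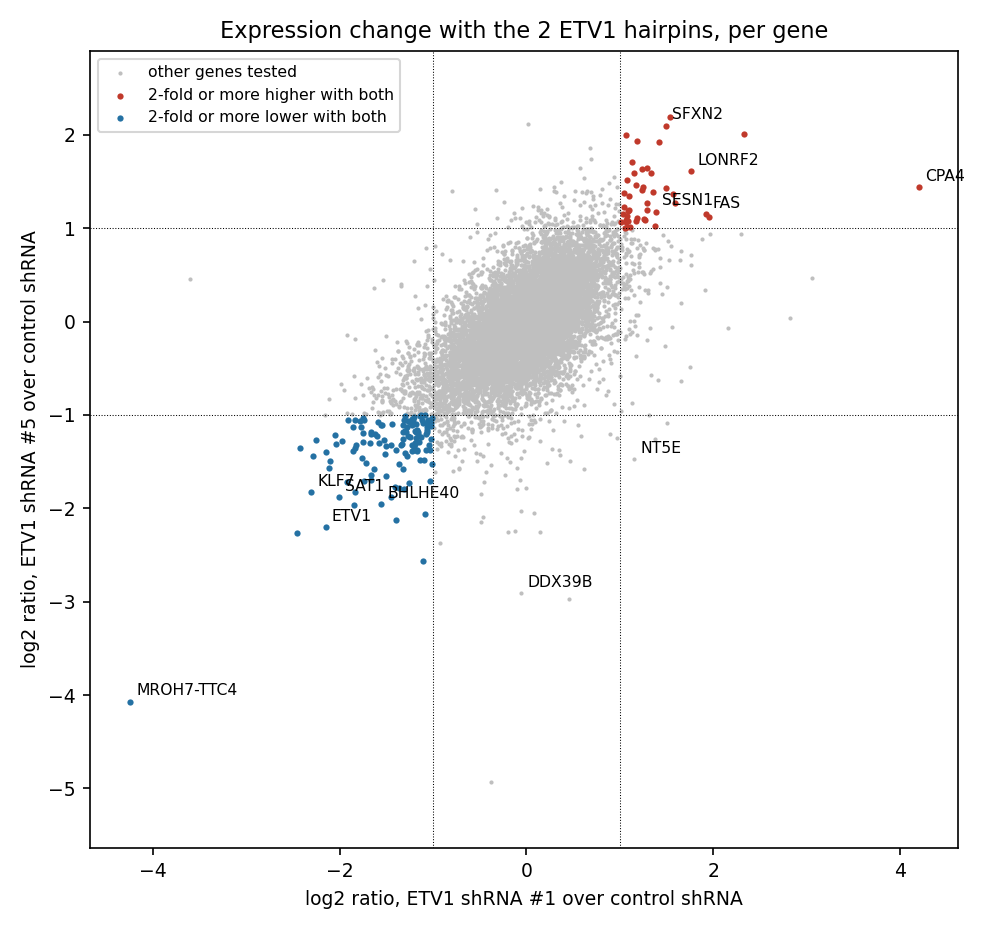
Log2 ratio to the control library for each of the 13024 genes tested, with ETV1 shRNA #1 on the horizontal axis and #5 on the vertical axis; each point is 1 gene, dotted lines mark log2 ratios of 1 and -1, and coloured points passed the 2-fold rule with both hairpins (45 higher, 125 lower). ETV1 lies at -2.15 and -2.20, and CPA4 lies far to the right at 4.20 with #1 and 1.44 with #5.

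The genes most reduced with both hairpins were ranked by the smaller of the log2 ratios. SAT1, which acetylates spermidine and spermine in polyamine breakdown, was at 778 RPM in the control library, 192 with #1 and 211 with #5 (log2 ratios -2.01 and -1.88). The transcription factor genes KLF7 (-2.30 and -1.83) and BHLHE40 (-1.55 and -1.95) were lower. So were ANGPTL4, encoding a secreted lipoprotein lipase inhibitor (-1.84 and -1.83), the collagen receptor gene MRC2 (-1.85 and -1.97) and DES, the gene of the intermediate filament protein desmin (-1.76 and -1.46). CCNG2, the cyclin G2 gene, had ratios of -1.72 and -1.51, and the arrestin-domain gene ARRDC4 had -1.51 and -1.66. LINC00326, a long non-coding RNA, had -2.11 and -1.57, and the zinc finger gene ZC3H6 had -1.45 and -1.88. The rule also named MROH7-TTC4, a readthrough transcript of neighbouring genes, at 22.3, 0.229 and 0.387 RPM. The overlapping rows MROH7 and TTC4 together went the other way, from 30.2 RPM to 70.2 and 62.9.

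Among the genes most increased with both hairpins, SFXN2, a mitochondrial transporter gene of the sideroflexin family, was at 3.75, 12.3 and 19.3 RPM in the control, #1 and #5 libraries (log2 ratios 1.49 and 2.10). SLC25A10, the mitochondrial dicarboxylate carrier, had ratios of 1.36 and 1.38. PDF, the mitochondrial peptide deformylase, had 1.29 and 1.64, and PYCRL, a proline synthesis enzyme gene, had 1.57 and 1.36. LONRF2 (1.76 and 1.61), TULP3, which takes part in transport into cilia (1.49 and 1.43), and SYBU, a syntaphilin-like transport adaptor gene (1.59 and 1.26), were also higher. The homeobox gene MSX2 had 1.25 and 1.44, and the keratin gene KRT13 had 1.42 and 1.92. MT1E, a metallothionein gene with near-identical relatives that can share its reads, had 1.33 and 1.59. CPA4, a carboxypeptidase gene, was at 17.5 RPM in the control library, 340 with #1 and 49.1 with #5. TAX1BP3 had 1.54 and 2.19, and it overlaps a readthrough row with P2RX5 that can share its reads.

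Taking both hairpin libraries as an arm of 2 against the control library, limma called 0 genes higher and 1 gene lower at an adjusted p under 0.05 over 13024 genes. The gene was MROH7-TTC4 (limma log2 difference -4.16, SE 0.29, adjusted p = 0.0307, lower in both hairpin libraries), which is uncertain as a readthrough row. ETV1 had a limma difference of -2.17 (SE 0.28) and an adjusted p of 0.444 over all genes, and 0.00232 adjusted over the list alone of ETS factors. If nothing changed and the model held, a share of 0.05 of the 13024 genes would have an unadjusted limma p under 0.05. At that p there were 1243 genes, 492 higher and 751 lower. With scaling by total reads that split was 358 higher and 902 lower. MROH7-TTC4 was no longer called, and 0 genes were lower, with a minimum of 5 RPM, with no filter or with a pseudocount of 0.1.

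Of the 30 gene lists with enough measured members, 12 had a median outside the matched range with #1 and 19 with #5. If genes varied independently, 1.5 would be expected for each. Genes of a list can vary together, so the excess over 1.5 does not measure an effect of the knockdown. Lists also lay outside that range when the hairpins were compared with each other, as given further below. Against the control library, the medians of 4 lists lay above the matched range and those of 5 lists below it with both hairpins. Unchanged libraries sharing a control, simulated with the hairpin variance, gave on average 0.085 lists above with both (range 0 to 1) and 0.12 below (range 0 to 1). Genes were drawn independently there, so shared variation within a list is left out, and the shared control may still contribute to these counts. Medians under 0.1 in size gave no firm direction, since another scaling turned the sign for ETS, epithelial, unfolded protein, cholesterol, respiratory chain, histone demethylase, RNA interference, ERK and YAP/TEAD genes with #1 and for ATF4 and YAP/TEAD genes with #5. No member of any list passed limma over all genes, so members called below are adjusted over the list alone. Each list was adjusted separately, with no correction across the 30 lists, and all calls share the 1 control library. Other members named were picked for large changes in the same direction with both hairpins, and do not stand for lists whose medians differed between the hairpins.

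Target genes of the tumour suppressor p53, for which HCT116 is wild type, were higher with both hairpins. The median log2 ratio of the 32 genes was 0.69 with #1 and 0.62 with #5, both at percentile 100, and 27 were above 0 with both hairpins. With #1, 10 were 2-fold higher, with #5 8, and 6 with both. By limma, 8 rose when adjusted over the list alone, and 0 over all genes. FAS, a death receptor gene, went from 8.44 RPM to 34.8 with #1 and 19.9 with #5, SESN1, a stress-response gene, from 13.9 to 37.9 and 32.7, TP53I3 from 6.34 to 27.5 and 14.9, and AEN, an apoptosis-enhancing nuclease gene, from 45.9 to 99.4 and 118. Each of these had a limma p of 0.0286 adjusted over the list alone.

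G1/S and DNA replication genes were also higher. Their 38 members had medians of 0.32 (percentile 99.8) with #1 and 0.61 (percentile 100) with #5, and 30 were above 0 with both. MCM10, a replication initiation gene, had log2 ratios of 0.94 and 1.05, the transcription factor gene E2F2 0.89 and 0.91, CHAF1A, a chromatin assembly gene, 0.75 and 0.90, and UHRF1 0.64 and 1.11. The 31 MYC target and ribosome biogenesis genes had medians of 0.44 (percentile 100) and 0.34 (percentile 99.9), with 26 above 0 with both. ODC1, the first enzyme of polyamine synthesis, was 263.6 RPM in the control library and 566 and 603 with the hairpins, and SRM, spermidine synthase, was 61.7, 133 and 105. In neither list did a member pass limma adjusted over the list alone.

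Replication-dependent histone genes were higher with both hairpins. Their 7 measured members, of 17 listed, had medians of 1.34 (percentile 100) with #1 and 0.79 (percentile 99.98) with #5. With both hairpins 6 members were above 0 and 1 below 0. With #1, 5 were 2-fold higher, with #5 0, and 5 rose by limma adjusted over the list alone, the smallest adjusted p being 0.0289. HIST1H2BK went from 17.5 RPM to 52.9 and 31.2, HIST1H1C from 7.23 to 14.4 and 14.1, and HIST2H2BE from 1.27 to 7.33 and 3.16. HIST2H2AA3 (log2 ratios 1.25 and 0.79) has a near-identical copy that can share its reads. Several members are low, and the medians depended on the pseudocount. With a pseudocount of 5 and #5 the histone median was 0.38, below those of G1/S (0.58) and p53 target genes (0.50).

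Glycolysis and hypoxia genes were lower with both hairpins. The 31 genes had medians of -0.44 with #1 and -0.45 with #5, both at percentile 0, and 22 were below 0 with both. With #1, 6 were 2-fold lower, with #5 4, and the same 4 genes, ANKRD37, P4HA1, ALDOC and NDRG1, with both. These 4 also fell by limma adjusted over the list alone. P4HA1, a collagen prolyl hydroxylase subunit gene, went from 94.6 RPM to 36.1 and 32.2, and ALDOC, a glycolytic aldolase gene, from 81.1 to 31.9 and 26.5 (limma p of 0.0118 adjusted over the list alone for both). NDRG1, a hypoxia-inducible gene, went from 419.8 to 197 and 99.5 (limma, 0.0497 adjusted over the list alone). ANKRD37, also hypoxia-inducible, went from 5.20 to 0.636 and 0.883.

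**Figure D2:**
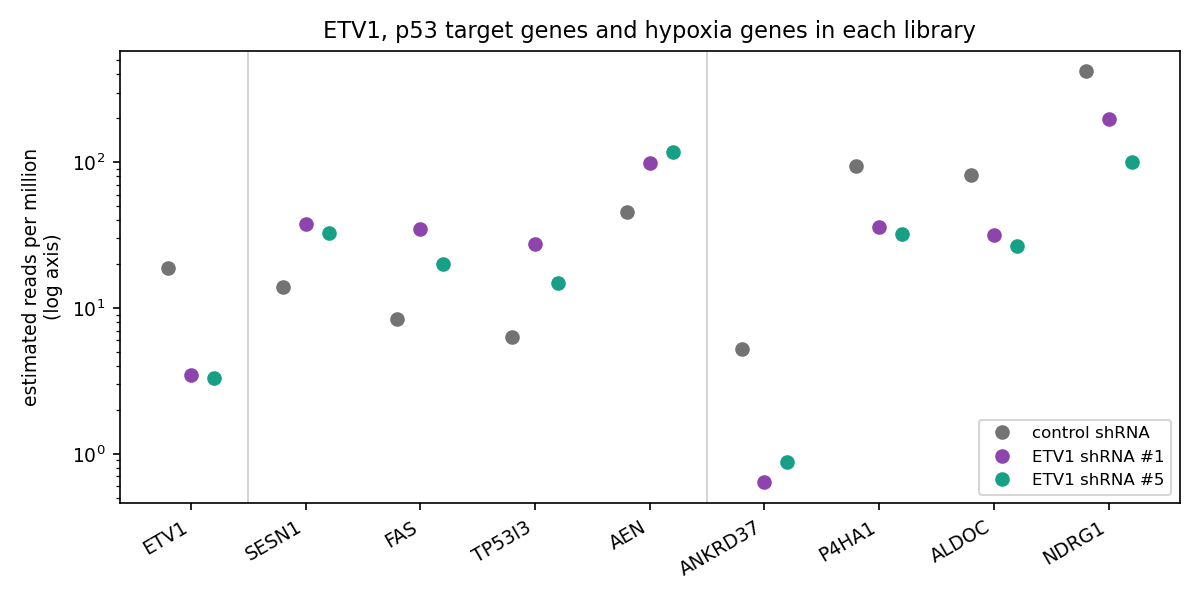
Estimated RPM on a log axis for ETV1, 4 p53 target genes and 4 hypoxia genes, with 1 point per library (control shRNA, ETV1 shRNA #1, ETV1 shRNA #5) and no error bars since each group had 1 library. ETV1 and the 4 hypoxia genes lie lower with both hairpins, and the 4 p53 target genes lie higher.

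Further lists lay below the matched range with both hairpins. The 38 G2/M and mitosis genes had medians of -0.39 (percentile 0) and -0.19 (percentile 0.03), with 26 below 0 with both. TOP2A, the mitotic topoisomerase gene, had log2 ratios of -0.60 and -0.68, the kinase gene NEK2 -0.93 and -0.54, the kinesin gene CENPE -0.61 and -0.54, and ANLN, which acts in cytokinesis, -0.53 and -0.64. The 22 immediate early genes had -0.22 (percentile 1.11) and -0.50 (percentile 0), where EGR3 had -1.13 and -1.24, EGR2 -0.98 and -0.995, and FOS -0.95 and -0.92, while BTG2, also a p53 target, had 1.76 and 0.71. The 18 matrix protease and other textbook ETS target genes had -0.44 (percentile 0.02) and -0.29 (percentile 0.70), but came inside the range with #5 (percentile 2.75) without the most changed member. In this list the membrane-bound protease gene MMP14 had -0.83 and -0.88, and the protease inhibitor genes TIMP2 and TIMP1 had -0.68 and -0.98, and -0.59 and -1.18. YAP1, a transcriptional coactivator gene, had 0.60 and 0.68. The 22 genes of the integrins and laminins list had -0.14 (percentile 0.52) and -0.46 (percentile 0). They came inside the range with #1 (percentile 4.25) after length and GC trends were subtracted. In that list ITGA7 had -1.20 and -0.70, and ITGB5 -1.10 and -0.65. Of the list's members that are neither integrins nor laminins, COL17A1 had 1.43 and 0.68, and CD151 0.52 and 0.67. In none of these 4 lists did a member pass limma adjusted over the list alone.

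**Figure D3:**
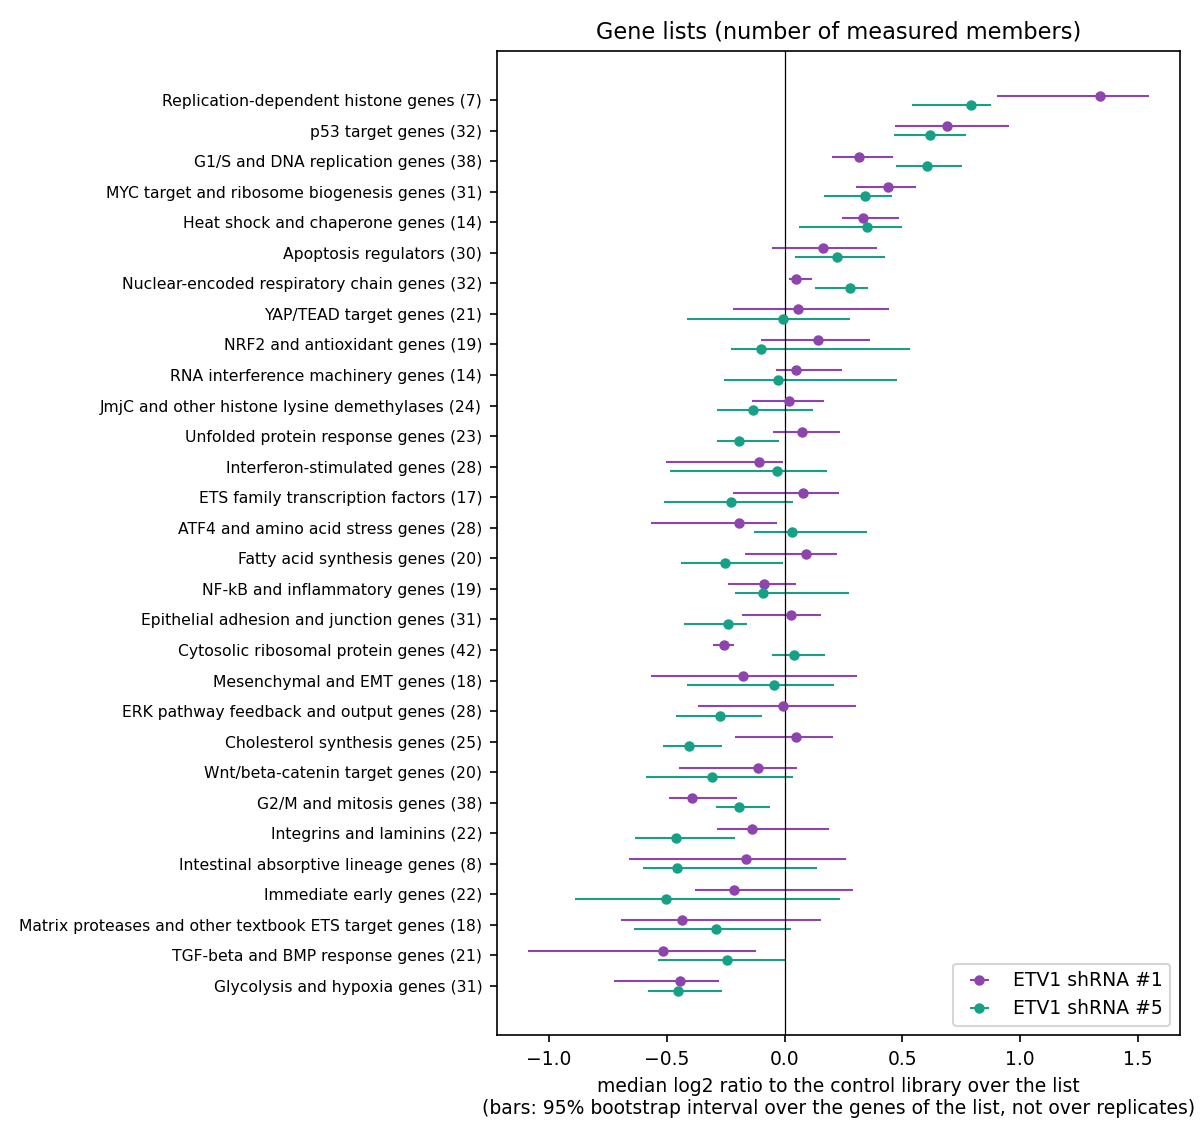
Median log2 ratio to the control library of each of the 30 gene lists with 5 or more measured members, with ETV1 shRNA #1 and #5 as separate points; bars are 95% bootstrap intervals over the genes of a list and are not replicate error, and the number of measured members follows each name. Replication-dependent histone genes (1.34 and 0.79) and p53 target genes (0.69 and 0.62) have the highest means of both medians, and glycolysis and hypoxia genes (-0.44 and -0.45) the lowest mean of both.

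Lists outside the matched range with 1 hairpin were mixed. The 21 TGF-beta and BMP response genes had medians of -0.51 (percentile 0) with #1 and -0.24 (percentile 2.78) with #5, the latter outside the range with a pseudocount of 0.1 (percentile 0.40) or after length and GC subtraction (0.27). By limma 4 fell and 1 rose when adjusted over the list alone, and those named, LTBP1, PMEPA1, SKIL and ID2, each had an adjusted p of 0.0372 over the list alone. SKIL, a feedback inhibitor of SMAD signalling, went from 28.2 RPM to 7.74 and 13.8, and ID2 from 216 to 111 and 118.0. The 28 ATF4 and amino acid stress genes had -0.19 (percentile 0.05) and 0.03 (percentile 42.2), with ALDH1L2 at -0.96 and -1.36, DDIT4 at -1.51 and -0.77, CTH at -0.78 and -0.76, and ATF5 at 0.71 and 1.21. The 42 cytosolic ribosomal protein genes had -0.26 (percentile 0) and 0.04 (percentile 25.7), with 19 below 0 with both. The 28 ERK pathway feedback and output genes had -0.01 (percentile 13.0) and -0.27 (percentile 0.05). In that list IER3, from 567 RPM to 243 and 216, and the EGF receptor ligand gene AREG, from 983 to 429 and 399, fell by limma adjusted over the list alone (adjusted p = 0.0275 for each). The 25 cholesterol synthesis genes had 0.05 (percentile 22.0) and -0.41 (percentile 0), with STARD4 at -0.93 and -0.46, and FDFT1 at -0.44 and -0.56. The 20 fatty acid synthesis genes had 0.09 (percentile 36.7) and -0.25 (percentile 0.26). The 31 epithelial adhesion and junction genes had 0.03 (percentile 21.3) and -0.24 (percentile 0.08), with CLDN3 at -0.98 and -1.61 and CDH1 at -0.47 and -0.84. The 20 Wnt/beta-catenin target genes had -0.11 (percentile 9.79) and -0.31 (percentile 0.37; 3.61 and so inside the range after length and GC subtraction), with SOX4 at -1.63 and -0.78 and DKK1 at -0.62 and -0.87. The 23 unfolded protein response genes had 0.08 (percentile 43.0) and -0.19 (percentile 1.37). The 17 measured ETS family factors, which include the targeted ETV1, had medians of 0.08 (percentile 46.5) and -0.23 (percentile 1.72), the mean with #1 being -0.12, and ETV4 was at -0.55 and -0.96. Without ETV1, its most changed member, this list was inside the range with #5 too (percentile 2.61).

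With #5, 3 more lists lay above the matched range. The 32 nuclear-encoded respiratory chain genes had 0.05 (percentile 11.2; -0.04 with scaling by total reads) with #1 and 0.28 (percentile 99.4) with #5, with COX7C at 0.52 and 1.40. The 30 apoptosis regulators had 0.16 (percentile 89.1) and 0.22 (percentile 99.0), with BBC3, encoding the p53-induced BH3 protein PUMA, at 1.06 and 1.06, BAX at 0.92 and 0.83, and BMF at -2.14 and -1.40. The 14 heat shock and chaperone genes had 0.33 (percentile 96.7) and 0.35 (percentile 99.0), with HSPA8 at 0.81 and 0.57. After length and GC subtraction all 3 came inside the range with #5, respiratory chain genes at percentile 92.6, heat shock genes at 93.98 and apoptosis regulators exactly at its upper edge. Heat shock genes also did without their most changed member (97.1).

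The remaining lists lay inside the matched range with both hairpins. The 28 interferon-stimulated genes had medians of -0.11 (percentile 23.02) and -0.03 (percentile 62.7), although IRF7 was at -1.35 and -0.86 and STAT2 at -0.74 and -0.71. The 19 NF-kB and inflammatory genes had -0.09 (percentile 25.9) and -0.09 (percentile 35.9). The 18 mesenchymal and EMT genes had -0.18 (percentile 3.14) and -0.05 (percentile 36.0), with #1 outside it without the most changed member (percentile 0.31) or after length and GC subtraction (1.30), and with LOXL2 at -0.98 and -1.14 and ZEB1 at 1.35 and 0.56. The 21 YAP/TEAD target genes had 0.06 (percentile 48.4) and -0.01 (percentile 48.4). The 19 NRF2 and antioxidant genes had 0.14 (percentile 61.2) and -0.10 (percentile 8.39), and the 24 histone lysine demethylase genes 0.02 (percentile 21.9) and -0.13 (percentile 4.59; 2.43 and so outside the range with a minimum of 5 RPM). The 8 intestinal absorptive genes had -0.16 (percentile 34.5) and -0.46 (percentile 2.68; 0.985 and so outside the range without the most changed member). The 14 RNA interference machinery genes had 0.05 (percentile 26.5; -0.04 with scaling by total reads) and -0.03 (percentile 25.5). For cholesterol, fatty acid and epithelial genes with #1, and for NRF2 and RNA interference genes with #5, the mean and the median had opposite signs. Too few members were measured for intestinal secretory genes (2 of 23), metallothioneins (3 of 8), and markers of fibroblasts (1 of 10), blood and immune cells (2 of 13) and endothelium (1 of 8). The 13 mitochondrially encoded genes had 0 measured, since the table analysed lists none of them.

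The hairpins were also compared with each other, to show what they did not share. Between them 188 genes were 2-fold or more higher and 121 lower with #1 than with #5. CPA4 was higher with #1 (340 against 49.1 RPM). GALNT5, a glycosyltransferase gene, was at 89.5 with #1 and 13.6 with #5. DHRS2, a short-chain dehydrogenase gene, was lower with #1 (2.96 against 14.8), as were TMSB15A (3.34 against 16.1), SCOC (27.5 against 101.9) and TPBG (38.03 against 134). DDX39B (129 with #1, 17.0 with #5), SPECC1L-ADORA2A (34.6 and 2.32), RAD51L3-RFFL (1.00 and 32.2) and DNAJC25-GNG10 (22.5 with #1, listed at 0 with #5) met the same rule. All 4 are readthrough rows or genes inside one, and their overlapping rows together went the other way (136 and 327, 62.6 and 80.9, 110 and 57.4, and 44.5 and 87.9). Among lists, medians of the difference between #1 and #5 lay at percentile 100 for replication-dependent histone (0.74), cholesterol synthesis (0.38) and integrin and laminin genes (0.37). They lay at percentile 0 for TGF-beta and BMP response (-0.47), ATF4 (-0.33), cytosolic ribosomal protein (-0.31), G1/S (-0.31) and G2/M genes (-0.28). Also above the matched range were ERK (percentile 99.7), epithelial (98.98) and unfolded protein response genes (97.7). Respiratory chain (percentile 0.04) and interferon-stimulated genes (0.33) lay below it, and the other lists inside it. For integrin and laminin and for G2/M genes, the difference exceeded in size the smaller median against the control library (-0.14 with #1 and -0.19 with #5). No replicate spread stands behind these differences.

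The authors' deposited table, from Z tests of 1 library against 1, lists 2749 genes for #1 against the control library (734 higher, 2015 lower) and 2935 for #5 (1136 higher, 1799 lower). It lists 2361 for #1 against #5 (1013 higher, 1348 lower), and 1002 in the same direction with both hairpins (257 higher, 745 lower). Genes passing all 3 tests are left out of these counts. Of the 45 genes higher with both hairpins in the RefSeq values, 37 had the same direction in both tests of the authors' deposited table, as did 101 of the 125 lower genes. Among genes matched between the sources, the sign was the same for 98.8% of 880 genes with #1 and 96.8% of 718 genes with #5 in the authors' deposited table. These matched genes are only part of the 2749 and 2935 listed there. Both sources come from the same 3 libraries, and the authors' table holds only genes changed 2-fold or more. The shared direction was thus largely set in advance and is no independent check.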

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

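For the readthrough loci and the control culture, the tests were chosen only after the results were seen. GALNT5, NT5E, KLK7 and MAOB moved in opposite directions with the hairpins, and each passed the 2-fold rule both ways; the difference was not tested, since each hairpin has 1 library. All 4 were higher with #1 and lower with #5, and 0 genes had the reverse pattern. GALNT5 had log2 ratios of 1.38 with #1 and -1.26 with #5. For NT5E, encoding the cell-surface nucleotidase CD73, the ratios were 1.15 and -1.47. KLK7, a secreted protease gene, had 1.51 and -1.08. MAOB, encoding monoamine oxidase B, had 1.31 and -1.002.

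Target genes of p53 were higher with both hairpins. After transcript length and GC content trends were subtracted, the list stayed at percentile 100 with both hairpins, which argues against those trends as the whole cause. The state of the control culture cannot be told apart from the knockdown, because 1 control library serves both hairpins. ETV1 loss is therefore an open candidate explanation beside a control culture with low p53 activity and off-target effects of the hairpins.

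Glycolysis and hypoxia genes were lower with both hairpins. After subtracting length and GC trends, the higher of the hairpins' percentiles was 0, which argues against those trends as the cause. A denser or less aerated control culture would give the same pattern, and with 1 control library it cannot be told apart from an effect of ETV1 loss.

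Named genes in readthrough loci included some of the largest changes. If reads of overlapping genes were assigned differently between libraries, the overlapping rows should move the other way by a similar amount. In 5 of 6 named loci (MROH7-TTC4, DNAJC25-GNG10, SPECC1L-ADORA2A, DDX39B and RAD51L3-RFFL), they did so by at least 0.5 of the change of the named row in RPM, with the hairpin of the larger change. The shares were 1.81, 1.32, 1.49, 1.59 and 3.04, so the overlapping rows gained more than the named row lost, and reassigned reads alone do not account for that excess. The count of 5 is consistent with reads shared between overlapping genes being assigned differently between libraries as part of the cause, while a rise of the overlapping genes themselves or a switch between transcripts of a locus stays open. For TAX1BP3 the share was 0.126, so shared reads leave most of its rise with #5 unexplained.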

How the results depend on the processing

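The authors' table, the length and GC subtraction and the removal of readthrough loci were chosen after seeing the data. No paired analysis was possible because each group had 1 library and replicate numbers came from accession order only. Leaving out a hairpin library would leave limma no residual degrees of freedom, and count-based tools from the plan were not run, since the values are not counts. Directions of ETV1, the named genes and list members and the lists outside the matched range with both hairpins held in every alternative run, while list medians close to 0 changed sign in some. Counts of changed genes moved with the thresholds. With a fold rule of 1.5, #1 had 989 higher and 1402 lower, #5 1095 and 1394, both hairpins 409 and 696, and #1 against #5 900 and 796. With a fold rule of 3 these were 20 and 71, 16 and 42, 2 and 11, and 43 and 16. A pseudocount of 5 gave 89 and 116 for #1, 84 and 116 for #5, 20 and 32 for both, and 110 and 46 for #1 against #5. A pseudocount of 0.1 gave 675 lower with #1, 522 lower with #5, 80 higher and 244 lower with both, and 263 lower with #1 than #5. A minimum of 5 RPM gave 257 lower with #1 and 78 lower with both. The authors' deposited table gave 734 and 2015 for #1, 1136 and 1799 for #5, 257 and 745 for both, and 1013 and 1348 for #1 against #5; it differs in gene model, test and scaling, and the cause was not tested. The limma count of lower genes went from 1 to 0 with a minimum of 5 RPM (511 lower at an unadjusted p under 0.05), no filter (1033) and a pseudocount of 0.1 (694). ETV1 was at -1.49 and -1.52 with a pseudocount of 5, as its construction shrinks low genes. The histone medians were 1.59 and 0.89 with a pseudocount of 0.1, and 0.83 and 0.38 with 5. Under scaling by total reads, 32 genes were higher and 162 lower with both hairpins, and the median of all genes shifted by -0.09 and -0.04. Without readthrough loci the counts were 42 and 120. The correlation ranged from 0.60 to 0.63. Of the 9 lists outside the matched range with both hairpins, 2 came inside it under 1 alternative each, matrix proteases with #5 (percentile 2.75, most changed member left out) and integrins and laminins with #1 (percentile 4.25, length and GC subtracted), and the histone list had too few members at a minimum of 5 RPM. Of the other lists, ETS and heat shock genes with #5 came inside without their most changed member, as did Wnt, apoptosis, respiratory chain and heat shock genes with #5 under length and GC subtraction. TGF-beta (#5), EMT (#1), absorptive (#5) and histone demethylase genes (#5) left the range under 1 or 2 alternatives. Among single genes and other lists, 1452 values under an alternative stayed close to the reported one and 48 moved. Low genes are limited by depth, since 1 read or fewer is listed as 0.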

Other observations

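Humanin-like MTRNR2L genes, nuclear copies of mitochondrial ribosomal RNA sequence, were higher with #1 than in the control library. MTRNR2L2 was at 2632 RPM in the control library, 5142 with #1 and 2105 with #5 (log2 ratios 0.97 and -0.32). MTRNR2L9 had 1.15 and 1.59, and MTRNR2L1 had 1.03 and 0.42. Their reads can be shared with one another and with the mitochondrial genome. The authors' deposited table lists 96 mitochondrial pseudogenes. There 64 were lower and 10 higher with #5 against the control library, 2 lower and 9 higher with #1, and 77 higher with #1 than with #5. These were picked after their values were seen.

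CCNG2, SESN3 and ARRDC4, each known to respond to FOXO factors or energy stress, were lower with both hairpins, SESN3 having log2 ratios of -1.86 and -1.39. A hypothesis from this is that FOXO and energy stress target genes were lower as a set. A list of 27 other such genes was written after those 3 had been seen but before its values as a set had been. Its 26 measured members had medians of -0.33 with #1 and -0.54 with #5, with 18 below 0 with both hairpins, and the higher of the percentiles was 0.03. KLHL24 had -1.68 and -1.30, MXI1 -0.97 and -0.93, and YPEL2 -0.86 and -1.28, while SESN1, also a p53 target, had 1.38 and 1.18. Glycolysis and hypoxia genes were also lower with both hairpins, and whether the FOXO list moved separately from hypoxia-responsive genes was not tested. Of the FOXO list's members, 5 also stand in other lists used here and may have been seen earlier. The 21 others had medians of -0.36 and -0.58. The pattern is consistent with lower output of such genes in both hairpin libraries, but the control culture may equally differ, and with 1 control library that stays open.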
